A study of Mus musculus with 20 samples.

How the data were processed

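Expression was measured in mouse oocytes and embryos of 4 later stages, with 4 arrays per stage and 20 in all, on the Affymetrix MOE430A array. Per the labels, total RNA was amplified by repeated in vitro transcription before hybridization. The deposited values are a linear probe-set intensity, scaled by the authors so that each array has the same trimmed mean, which was 149.97 to 149.98 on every array when 2% of the values were trimmed at each end. The software, background step and detection calls behind the intensities are not given in the sources used here. No array was left out, and 0 pairs of arrays of 190 held identical values.

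Groups were taken from the stage in each title. The titles number the replicates 1 to 4 and name no collection day or batch, so no block entered the model. Of 22690 probe sets, 64 controls were left out of the tests. The remaining 22626 carried 1 gene symbol in 20380 cases, several in 691 and none in 1555, which covers 12393 genes. Intensities were transformed as log2(value + 12.15), where the constant is the pooled median intensity of 48.6 divided by 4, without further normalization. Fold changes on this scale understate the change of genes with low intensity. The order of the largest changes holds for this constant only, and the genes were not ranked again with others. Probe sets above an intensity of 32.9, the pooled 40th percentile, on at least 4 arrays were tested. This kept 17208 probe sets, 15738 with 1 symbol, for 10257 genes.

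One linear model of all 5 stages was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 15 residual degrees of freedom). Differences are the later stage minus the earlier one, for 4 consecutive transitions and for oocyte to blastocyst. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 in limma's two-sided moderated test were called, within each comparison. Errors of log2 changes are moderated standard errors, and errors of intensities are SDs over 4 arrays. Where a gene had several tested probe sets, the one with the highest mean log2 value stood for the gene. Probe sets of a gene do not always move alike. Among the genes named at the oocyte to 1-cell transition, 1 of 3 probe sets of Psmb1, 2 of 4 of Rpl41 and 2 of 3 of Rps20 carried the call of the representative.

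The 21 gene lists were fixed before the data were examined. They held oocyte-specific and maternal-effect genes, 2-cell stage activation genes, trophectoderm, pluripotency and primitive endoderm markers, cytosolic ribosomal proteins, ribosome biogenesis, splicing factors, proteasome, oxidative phosphorylation, glycolysis, cholesterol synthesis, cell junctions, M phase, DNA replication, chromatin modifiers, mRNA decay, p53 targets, and markers of cumulus, sperm, and oviduct or blood cells. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 105 tests. Members were also counted with p-values adjusted over the list alone. All counts are over the members tested, such as 14 of 28 listed 2-cell activation genes, 43 of 80 ribosomal protein genes and 24 of 40 oocyte-specific genes. A gene that is low at most stages passes the intensity filter only where it is high, which favours members that change.

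Genes were named by a rule fixed before the data were examined. At each transition the rule took the 10 largest rises and 10 largest falls among called probe sets with 1 established gene symbol, no overlap between the 4 values of both stages and a higher mean above the median of tested probe sets. It added up to 2 risen and 2 fallen members per list, and a fixed set of stage markers, of which Zscan4c was not tested. The text leaves out some of these genes for length and adds none to the comparisons.

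The procedure was tested on simulated data with the spread of these arrays. Planted changes of 2 on the log2 scale were found in 92.4% to 98.5% of cases, changes of 1 in 43.3% to 58.2% and changes of 0.5 in 1.49% to 7.46%, with 4 to 8 false calls among 17208 probe sets. Each simulated comparison held 66 or 67 planted changes of each size and no other stage effect. At the real transitions 5399 to 8327 probe sets were called. The adjusted threshold is stricter where few probe sets change, so these rates and false calls do not describe the real comparisons. A list shift planted in the proteasome genes was found, and 0 other lists were called. The simulation did not test lists whose genes vary together, so it does not show how often such lists are called by chance. On the real arrays the estimated correlation within a list ran from 0.000692 for pluripotency markers to 0.377 for ribosomal proteins. Settings chosen before the data were examined and run beside these were quantile normalization, centring on the array median, a pseudocount of 3.04 or 48.6, no filter or a filter at the 60th percentile (71.8), a 2-fold threshold, 1 probe set per gene, a fit on the compared stages alone, eBayes without the trend, the replicate number as a block, and leaving out each replicate. Scaling to the hybridization controls, and the count of probe sets that fell at the 1-cell stage and rose at the 2-cell stage, were chosen after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.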

Results

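Transcript levels were measured in mouse oocytes and in embryos at the 1-cell, 2-cell, 8-cell and blastocyst stages on 20 MOE430A expression arrays, 4 per stage. The labels give total RNA that was amplified by repeated in vitro transcription. They do not give the number of embryos behind each array or whether the replicates came from separate collections. The median intensity per array averaged 46.1 ± 6.53 in oocytes, 48.5 ± 4.94 at the 1-cell stage, 53.1 ± 2.48 at the 2-cell stage, 52.5 ± 6.88 at the 8-cell stage and 43.1 ± 5.49 in blastocysts (SD, n = 4 each). The share of probe sets above the intensity filter ranged from 56.8% ± 3.59 in blastocysts to 62.8% ± 1.28 at the 2-cell stage. The comparisons follow the stages in order and so describe how transcript levels changed from the oocyte to the blastocyst.

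Arrays of the same stage correlated at 0.931 to 0.971 across probe sets, where probe sets are not independent replicates. The mean correlation between stages was 0.873 for oocyte and 1-cell arrays, 0.732 for 1-cell and 2-cell arrays, 0.727 for 2-cell and 8-cell arrays and 0.834 for 8-cell and blastocyst arrays. The lowest mean, 0.461, was between 1-cell and 8-cell arrays. Signs of RNA quality and of amplification also differed between stages. The ratio of 3′ to 5′ signal for beta-actin was 4.74 ± 0.364 in oocytes, 4.24 ± 1.2 at the 1-cell, 4.63 ± 0.622 at the 2-cell and 3.67 ± 0.234 at the 8-cell stage, and 1.99 ± 0.325 in blastocysts (SD, n = 4). The same ratio for Gapdh was 1.28 ± 0.469 at the 8-cell stage and between 4.70 and 5.81 on average at the other stages. The intensity of the added cre hybridization control was 6202 ± 961 in oocytes, 12080 ± 2618 at the 1-cell, 10360 ± 1892 at the 2-cell and 16280 ± 3736 at the 8-cell stage, and 7467 ± 1557 in blastocysts. The p-values below measure only the spread between these samples, which may be technical, and the number of arrays limits their precision.

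**Figure D1:**
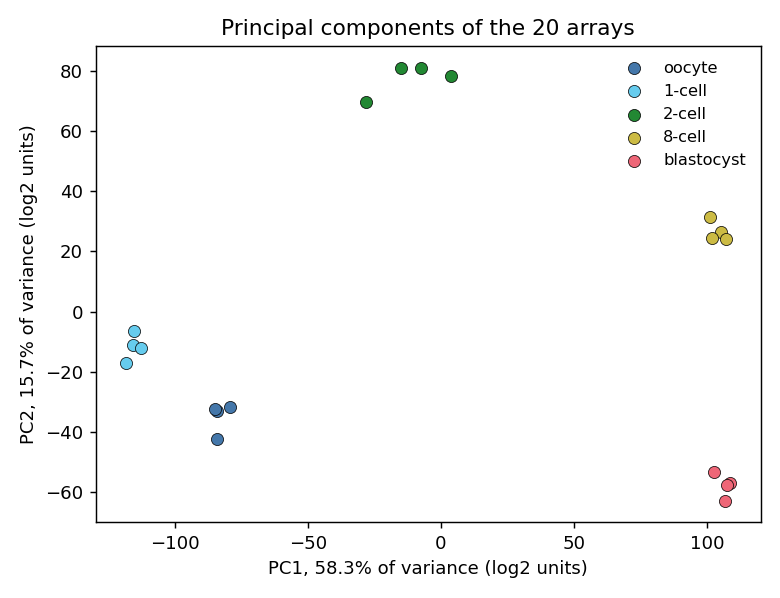
Each point is 1 array, placed by its scores on PC1 and PC2 (log2 units) and coloured by stage. The 4 arrays of every stage lie together, and the axes carry 58.3% and 15.7% of the variance.

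**Figure D2:**
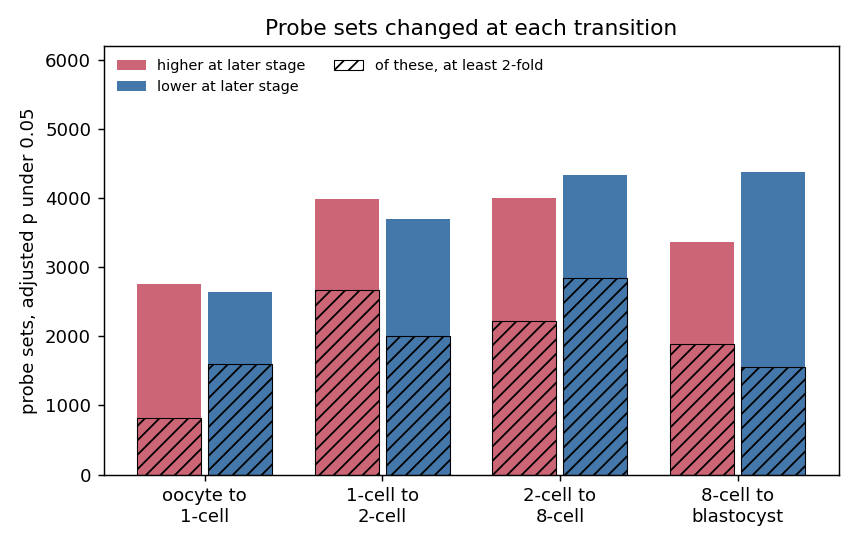
Bars give the number of probe sets with an adjusted p under 0.05 at each transition, higher (red) or lower (blue) at the later stage, and the hatched part the probe sets that changed at least 2-fold. The 2-cell to 8-cell transition has the highest total, 8327 probe sets, and the oocyte to 1-cell transition the lowest, 5399, whereas under scaling to the hybridization controls oocyte to 1-cell has the highest, 7872, and 1-cell to 2-cell the lowest, 5855.

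From the oocyte to the 1-cell stage, transcripts for the translation and respiration machinery fell as groups, and oocyte-specific transcripts moved in both directions on the deposited scale. Of the cytosolic ribosomal protein genes, 37 of 43 fell and 0 rose, with a median log2 change of -2.09. Rps20 fell by 4.04 ± 0.20 on the log2 scale (SE, n = 4 arrays per stage), from an intensity of 1826 ± 422 to 99.2 ± 21.3 (SD). Other transcripts may share this probe set. The changes of the 3 probe sets of Rps20 ran from -4.04 to -0.69, and 2 of them carried the call. Of the oxidative phosphorylation genes, 56 of 71 fell and 3 rose, with a median of -1.61. Zp3, which encodes a protein of the zona pellucida around the oocyte, fell by 2.23 ± 0.18, whereas Gdf9, an oocyte growth factor, had a log2 change of 0.28 ± 0.15 that did not pass the test (adjusted p = 0.192), turned to -0.26 without a call under quantile normalization, and turned to a called -0.74 (adjusted p = 0.0214) under scaling to the hybridization controls.

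Adjusted over the list alone, 38 ribosomal protein genes fell and 0 rose, and 57 oxidative phosphorylation genes fell and 4 rose. Both lists passed the camera test (adjusted p = 6.31e-34 and 7.88e-29) and also passed with an estimated correlation (0.0247 and 0.0164). The respiratory chain genes Atp5o and Ndufv3 fell by 4.06 ± 0.25 and 3.98 ± 0.27. Ndufa10 and Sdha, which encode subunits of complex I and complex II, had log2 changes of 1.46 ± 0.19 and 1.07 ± 0.20, and neither call held under scaling to the hybridization controls (0.46 and 0.07). Of the proteasome genes, 21 of 36 fell and 5 rose, and the counts adjusted over the list alone were equal. Psmd14, a deubiquitinating subunit, fell by 2.70 ± 0.18. The proteasome list passed at an adjusted p of 5.05e-07, which became adjusted p = 0.177 with an estimated correlation. Of the ribosome biogenesis genes, 20 of 45 fell and 3 rose (22 and 6 adjusted over the list alone). That list passed at 0.000748, with adjusted p = 0.383 with an estimated correlation. The 1-cell arrays that carried these lower signals also carried a high signal for 18S ribosomal RNA, with its middle probe set at an intensity of 12670 ± 1877 against 196 ± 57.6 in oocytes (SD, n = 4).

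Oocyte-specific and maternal-effect genes moved in both directions, with 10 of 24 higher, 10 lower and the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.774). Its median of 0.165 became -0.0152 under quantile normalization and -0.774 under scaling to the hybridization controls, which ended the rises of Omt2a (1.17 to 0.16) and Tcl1b1 (1.12 to 0.10) and turned that of Tcl1 (0.98 to -0.040), a call that quantile normalization also ended (0.41). Zp2 fell by 3.18 ± 0.19 and Zp1 by 2.58 ± 0.19. Mos, the kinase that holds the egg in meiotic arrest, fell by 1.53 ± 0.42, and Nlrp5, a maternal-effect gene, fell by 1.17 ± 0.21. Dnmt1, the maintenance DNA methyltransferase, fell by 1.10 ± 0.18. The mRNA decay and translational control genes had 12 of 37 higher and 4 lower (13 and 4 adjusted over the list alone), and the list passed upward at 0.0102. Its adjusted p = 0.131 with an estimated correlation, and its median of 0.41 became -0.58 under scaling to the hybridization controls. Ybx1, which encodes an RNA-binding protein, had a log2 change of 1.56 ± 0.14, and Cnot6l, a deadenylase subunit, 1.34 ± 0.20, both calls that this scaling ended (0.54 and 0.33). Under the naming rule, Upp1, uridine phosphorylase, fell by 4.72 ± 0.24, the largest fall, and Cox17, a copper chaperone of cytochrome oxidase, fell by 4.56 ± 0.26. The largest rise was that of Pfn1, which encodes the actin-binding protein profilin, at 2.34 ± 0.33, followed by the homeobox gene Hoxa7 at 2.09 ± 0.32. Splicing factor genes had 11 of 38 higher and 12 lower, again equal when adjusted over the list alone, and did not pass (adjusted p = 0.337), but were called lower under scaling to the hybridization controls (median -1.02, adjusted p = 0.0192). DNA methylation and chromatin modifier genes had 12 of 38 higher and 8 lower (13 and 10 adjusted over the list alone; adjusted p = 0.398).

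In all, 5399 of 17208 probe sets passed, 2760 higher and 2639 lower, and 2420 of them changed at least 2-fold, 819 higher and 1601 lower. Of the lists, 5 of 21 passed, and the estimated correlation kept 2. The median, mean and test differed in sign for the oocyte-specific, pluripotency, primitive endoderm, glycolysis, cholesterol synthesis and p53 lists, none of which passed. Scaling to the hybridization controls moved the median of all genes by -0.82 and left 0.699% of 7872 called probe sets higher, against 51.1% in the fit on the deposited scale.

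From the 1-cell to the 2-cell stage, genes known to switch on at zygotic genome activation rose and oocyte-specific transcripts fell. Of the 14 tested 2-cell stage activation genes, from 28 listed, 12 rose and 1 fell, with a median log2 change of 2.22 and the same counts adjusted over the list alone. Zfp352, a zinc finger gene of the 2-cell stage, rose by 5.99 ± 0.28, from an intensity of 19.6 ± 7 to 1994 ± 365 (SD, n = 4). Of the ribosomal protein genes, 39 of 43 rose and 1 fell, with a median of 2.56, in a list whose call ended with an estimated correlation (adjusted p = 0.0613). Of the oocyte-specific genes, 16 of 24 fell and 1 rose, with a median of -1.12 and the same counts adjusted over the list alone.

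The activation list passed at an adjusted p of 9.21e-06 and the oocyte-specific list at 5.33e-06, and both held with an estimated correlation (0.0164 and 0.0266). Tdpoz1 rose by 4.57 ± 0.28 and Hspa1b, an inducible heat shock protein gene, by 3.27 ± 0.42. The member that fell was Arg2, mitochondrial arginase, by 1.32 ± 0.21. Among the oocyte genes, H1f8, the oocyte linker histone, fell by 5.49 ± 0.24, Mos by 4.74 ± 0.42 and Gdf9 by 2.66 ± 0.15. Dnmt1 fell by 2.32 ± 0.18 and the de novo methyltransferase Dnmt3a by 1.90 ± 0.25. Dppa3, a maternal factor that protects DNA methylation, had a change of -0.27 ± 0.17 that did not pass (adjusted p = 0.22) and became 0.18 under quantile normalization, also without a call.

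Rps20 rose by 4.22 ± 0.20 and Rpl41 by 4.79 ± 0.44, both on probe sets that other transcripts may share. Rpl37 fell by 1.73 ± 0.23. The ribosomal protein list passed at 1.16e-22 with the preset correlation (40 higher and 1 lower adjusted over the list alone). Of the ribosome biogenesis genes, 33 of 45 rose and 2 fell (34 and 2 adjusted over the list alone), with a median of 1.36. Polr1c, a subunit of RNA polymerases I and III, rose by 4.91 ± 0.20. That list passed at 7.74e-11, with adjusted p = 0.0805 with an estimated correlation. Oxidative phosphorylation genes had 33 of 71 higher and 16 lower (35 and 16 adjusted over the list alone). Uqcrfs1, the Rieske protein of complex III, rose by 3.20 ± 0.21, and Uqcrc2 of the same complex fell by 2.69 ± 0.23. The list passed at 0.00943, with adjusted p = 0.607 with an estimated correlation. The signal of the same 18S ribosomal RNA probe set, high at the 1-cell stage, was 639 ± 116 at the 2-cell stage (SD, n = 4).

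Inner cell mass and pluripotency markers had 12 of 23 higher and 2 lower, equal when adjusted over the list alone. Dppa4 rose by 4.18 ± 0.17 and Klf4, a transcription factor of pluripotent cells, by 2.93 ± 0.20, while Sall4 fell by 1.18 ± 0.21. This list passed at 0.0156, with adjusted p = 0.0599 with an estimated correlation. Of the p53 target and apoptosis genes, 15 of 27 rose and 3 fell, also when adjusted over the list alone. Sesn2, a stress-induced gene, rose by 3.96 ± 0.32, and the pro-apoptotic gene Bid rose by 2.90 ± 0.28. Camera called the list at 0.00543, with adjusted p = 0.156 with an estimated correlation and 0.0817 under the stricter intensity filter. Of the M phase genes, 20 of 37 fell and 8 rose, again with equal counts adjusted over the list alone. Bub1b, a spindle checkpoint kinase, fell by 4.32 ± 0.21, whereas Cdk1 rose by 2.71 ± 0.18. This list passed at 0.0242, with adjusted p = 0.156 with an estimated correlation, and the call also ended under quantile normalization (0.201) and under scaling to the hybridization controls (0.0565).

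With the constant of 12.15, the largest rises were those of Ctsl, the lysosomal protease cathepsin L, by 7.08 ± 0.19, Selenos by 6.96 ± 0.19 and the nucleoside diphosphate kinase gene Nme2 by 6.95 ± 0.20. Pramel7 rose by 6.91 ± 0.15 and Tomm20, a mitochondrial import receptor, by 6.69 ± 0.17. The junction gene Epcam rose by 5.22 ± 0.20, and Cdh1, which encodes E-cadherin, fell by 2.16 ± 0.21. Junction and polarity genes had 7 of 33 higher and 10 lower, equal when adjusted over the list alone, and did not pass (adjusted p = 0.854). Cholesterol synthesis genes had 9 of 18 higher and 7 lower, equal when adjusted over the list alone, and did not pass (adjusted p = 0.996). Sqle rose by 2.44 ± 0.17 and Idi1 fell by 2.32 ± 0.21, both enzymes of that pathway. Ovgp1, the oviduct-specific glycoprotein gene and a marker of another cell type, rose by 2.46 ± 0.68 beside these changes, from 74.2 ± 26.5 to 495 ± 242 (SD, n = 4), with a probe set that other transcripts may share.

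In all, 7693 probe sets passed, 3992 higher and 3701 lower, and 4676 changed at least 2-fold, 2677 higher and 1999 lower. Of the lists, 8 of 21 passed, and the estimated correlation kept 2. The median, mean and test differed in sign for the primitive endoderm, proteasome, glycolysis, cholesterol synthesis, junction, sperm and oviduct lists, none of which passed. Scaling to the hybridization controls moved the median of all genes by 0.16 and gave 64.8% higher of 5855 called. Centring on the array median moved the median by -0.12 and gave 44.25% higher of 8045 called. Quantile normalization gave 46.23% of 8187, against 51.89% on the deposited scale, so the majority turned under both.

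**Figure D3:**
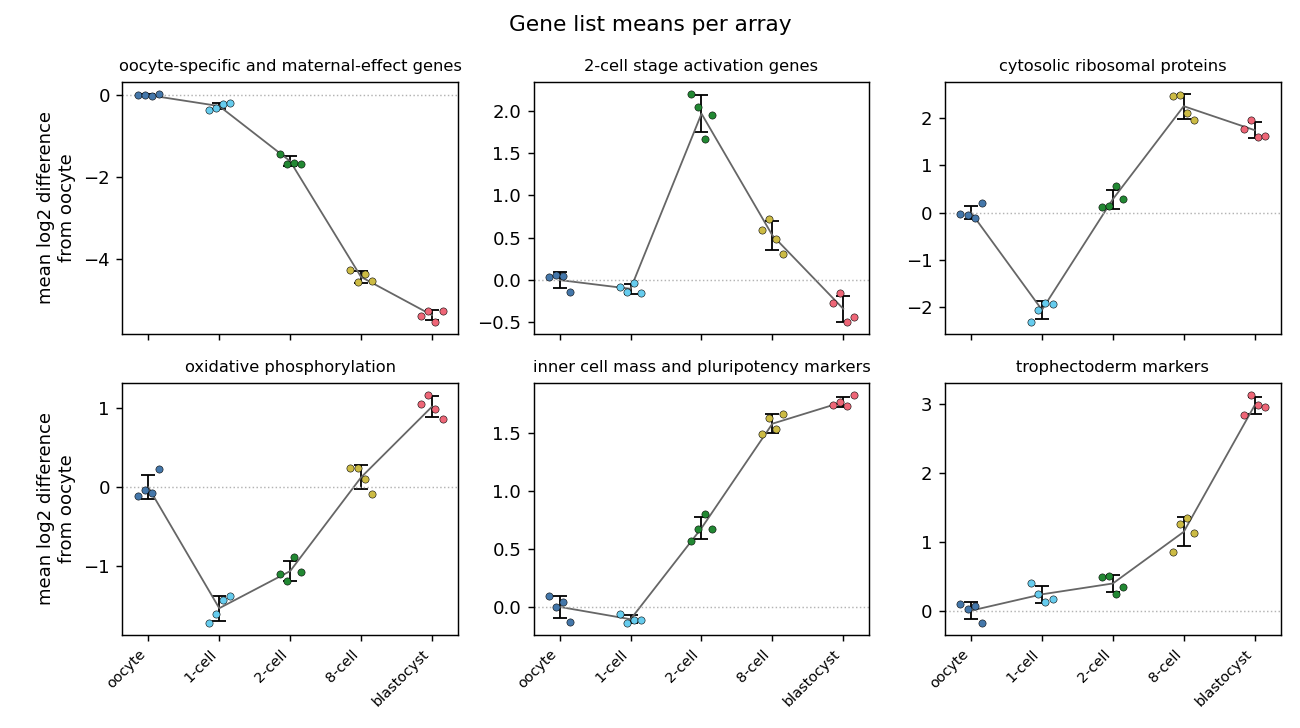
Mean log2 difference from the oocyte over the tested members of 6 gene lists (vertical axes), by stage, on the deposited scale. Points are arrays, lines join the stage means and bars give the SD over 4 arrays. The ribosomal protein list lies at -2.07 at the 1-cell stage and at 2.26 at the 8-cell stage, and under scaling to the hybridization controls its fall from the 8-cell stage to the blastocyst turns.

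From the 2-cell to the 8-cell stage, oocyte-specific transcripts fell further, several 2-cell transcripts fell and pluripotency markers rose. Of the oocyte-specific genes, 21 of 24 fell and 0 rose, with a median log2 change of -2.20 and the same counts adjusted over the list alone. Btg4, an adaptor for deadenylation of maternal mRNA, fell by 6.02 ± 0.23, from an intensity of 5470 ± 1542 to 72.6 ± 27.1 (SD, n = 4). Nanog, a transcription factor of pluripotent cells, rose by 4.07 ± 0.28 and Gata6, a factor of the primitive endoderm, by 3.77 ± 0.18. Cdx2, the trophectoderm factor, rose by 2.29 ± 0.33, to 131 ± 84.1.

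The oocyte-specific list passed at an adjusted p of 1.41e-13 and held with an estimated correlation (0.00257). Omt2a fell by 5.79 ± 0.18, Nlrp5 by 3.65 ± 0.21, Gdf9 by 2.95 ± 0.15 and Zp3 by 2.27 ± 0.18. Of the 2-cell stage activation genes, 8 of 14 fell and 3 rose (9 and 3 adjusted over the list alone). Zfp352 fell by 5.17 ± 0.28 and Tcstv3 by 3.67 ± 0.28, while the translation initiation factor gene Eif1a rose by 2.08 ± 0.21. As a list, these genes passed at 0.0236, with adjusted p = 0.156 with an estimated correlation and 0.069 under the stricter intensity filter. Of 3992 probe sets that rose at the 2-cell stage, 1075 fell again by the 8-cell stage. Independent lists would share 1005, and both comparisons use the 2-cell arrays. With these arrays divided between both comparisons, 749 to 895 probe sets were shared. No count for independent lists was made for the divided arrays. At an unadjusted p under 0.05 the count was 1260, and data simulated without stage effects gave 90.3 on average over 50 draws. Those draws hold no changed probe sets, so they do not give the overlap to expect of long lists. The count of 1075 lay near the 1005 of independent lists. The 2-cell activation genes were over-represented among the 640 genes with this course, with 7 of 14 (Fisher's exact test, adjusted p = 0.000175).

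Pluripotency markers had 14 of 23 higher and 2 lower, equal when adjusted over the list alone, and the list passed at 0.000617 and with an estimated correlation (0.0128). Tdgf1, a Nodal co-receptor, rose by 2.95 ± 0.27, and Tcl1, abundant in the oocyte, fell by 4.88 ± 0.20. Trophectoderm markers had 11 of 27 higher and 1 lower, again equal when adjusted over the list alone. Aqp3, a water channel, rose by 3.01 ± 0.24, Krt18 by 2.20 ± 0.23 and Krt8 by 1.63 ± 0.26, the last pair encoding keratins of simple epithelia. The list passed at 0.00673, with adjusted p = 0.207 with an estimated correlation, and its median of 0.45 became -0.02 under scaling to the hybridization controls. Junction and polarity genes had 12 of 33 higher and 5 lower, equal when adjusted over the list alone, and did not pass (adjusted p = 0.0619). That list was called higher under the smaller pseudocount (adjusted p = 0.0463), the stricter filter (0.0322) and scaling to the hybridization controls (0.041, with a median of -0.14). Primitive endoderm markers had 4 of 22 higher and 6 lower, equal when adjusted over the list alone, and did not pass (adjusted p = 0.982), and beside the rise of Gata6, Srgn fell by 3.01 ± 0.24 and Hhex fell by 1.45 ± 0.16. Gja1, which encodes the gap junction protein connexin 43, rose by 3.56 ± 0.34 and Cdh1 by 2.03 ± 0.21.

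Ribosomal protein genes rose in 42 of 43 cases with 0 lower, also adjusted over the list alone, and a median of 2.00. This list passed at 1.16e-22, with adjusted p = 0.0613 with an estimated correlation. Rpl14 rose by 2.99 ± 0.26. Oxidative phosphorylation genes had 57 of 71 higher and 2 lower (61 and 2 adjusted over the list alone). Uqcrb rose by 2.83 ± 0.20. Camera called the list at 1.41e-15, with adjusted p = 0.0712 with an estimated correlation. Of the proteasome genes, 31 of 36 rose and 3 fell (32 and 3 adjusted over the list alone). Psmb3 rose by 3.48 ± 0.19, and Psme4, an activator of the proteasome in germ cells, fell by 2.94 ± 0.20. As a list, these genes passed at 6.76e-11, with adjusted p = 0.0932 with an estimated correlation. Splicing factor genes had 24 of 38 higher and 1 lower, equal when adjusted over the list alone, and passed at 5.05e-07 and with an estimated correlation (0.0128). Srsf3 rose by 2.94 ± 0.19. Ribosome biogenesis genes had 21 of 45 higher and 3 lower, equal when adjusted over the list alone, and passed at 0.00178, with adjusted p = 0.431 with an estimated correlation and a median of 0.43 that became -0.06 under scaling to the hybridization controls. These groups rose on the arrays where the Gapdh ratio of 3′ to 5′ signal was lowest, 1.28 ± 0.469, whereas the beta-actin ratio there was 3.67 ± 0.234.

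The mRNA decay and translational control genes had 19 of 37 lower and 4 higher, equal when adjusted over the list alone. Lsm14b, which encodes an RNA-binding protein of oocytes, fell by 3.97 ± 0.19. The list passed at 0.00641, with adjusted p = 0.105 with an estimated correlation. Of the M phase genes, 17 of 37 fell and 3 rose, equal when adjusted over the list alone, with Plk4, the centriole duplication kinase, lower by 2.89 ± 0.19. This list passed at 0.0242, with adjusted p = 0.156 with an estimated correlation and 0.0777 under the stricter filter. DNA replication genes had 19 of 46 higher and 12 lower, equal when adjusted over the list alone, and did not pass (adjusted p = 0.307). Uhrf1, the partner of Dnmt1, fell by 2.96 ± 0.18. The largest rises under the naming rule were those of Bhmt of methionine synthesis by 5.78 ± 0.30, the pantetheinase gene Vnn1 by 5.37 ± 0.22, Fbp2 of gluconeogenesis by 5.13 ± 0.27, and Hadh and Acadl of fatty acid oxidation by 4.81 ± 0.38 and 4.69 ± 0.18. In the largest falls with the constant of 12.15, Pld1, a phospholipase D, fell by 6.51 ± 0.23 and Rfpl4 fell by 6.32 ± 0.25.

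In all, 8327 probe sets passed, 3995 higher and 4332 lower, and 5064 changed at least 2-fold, 2222 higher and 2842 lower. Of the lists, 11 of 21 passed, and the estimated correlation kept 3. The median, mean and test differed in sign for the cholesterol synthesis, p53 and sperm lists, none of which passed. Scaling to the hybridization controls moved the median of all genes by -0.41 and gave 23.2% higher of 6923 called, against 48.0% on the deposited scale. Centring on the array median gave 51.85% higher of 8540 and quantile normalization 51.68% of 8923. Dppa3 had a change of 0.07 ± 0.17 that did not pass, and under quantile normalization it was called in the other direction, at -0.81.

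From the 8-cell stage to the blastocyst, genes of the trophectoderm epithelium rose, as did the list of glycolysis and glucose uptake genes. Cell junction and respiratory genes rose as lists whose calls ended with an estimated correlation (adjusted p = 0.0599 and 0.0624). Of the trophectoderm markers, 22 of 27 rose and 4 fell, with a median log2 change of 1.97 and the same counts adjusted over the list alone. Krt18 rose by 3.79 ± 0.23, from an intensity of 396 ± 159 to 5346 ± 688 (SD, n = 4), Krt8 by 3.64 ± 0.26 and Cdx2 by 1.95 ± 0.33. Slc2a3, the glucose transporter of the trophectoderm, rose by 3.27 ± 0.22. Sox2, a factor of the inner cell mass, rose by 1.99 ± 0.23, and Dnmt3b, a de novo DNA methyltransferase, by 1.59 ± 0.19.

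The trophectoderm list passed at an adjusted p of 6.54e-12 and held with an estimated correlation (0.00921). Id2, a repressor of bHLH factors, rose by 4.82 ± 0.39 and the fatty acid-binding protein gene Fabp3 by 4.16 ± 0.21, while Tead4 fell by 1.87 ± 0.24. Glycolysis and glucose uptake genes had 11 of 17 higher and 3 lower, equal when adjusted over the list alone, and passed at 0.000466 and with an estimated correlation (0.0482). Pkm, pyruvate kinase, rose by 3.47 ± 0.31 and Hk1 fell by 2.49 ± 0.31. Junction and polarity genes had 19 of 33 higher and 3 lower (19 and 4 adjusted over the list alone), with a median of 0.97. The connexin gene Gjb5 rose by 3.82 ± 0.28, the desmosomal cadherin gene Dsg2 by 3.56 ± 0.28 and Cdh1 by 0.97 ± 0.21. Camera called the list at 2.56e-07 with the preset correlation. Oxidative phosphorylation genes had 53 of 71 higher and 0 lower (55 and 0 adjusted over the list alone). Ndufa3 rose by 1.93 ± 0.19. As a list, these genes passed at 1.62e-16 with the preset correlation. The ratio of 3′ to 5′ signal for beta-actin was lowest on these blastocyst arrays, at 1.99 ± 0.325, whereas the Gapdh ratio was highest on them, at 5.805 ± 1.962.

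Pluripotency markers went both ways, with 9 of 23 higher and 7 lower (9 and 8 adjusted over the list alone), and the list did not pass (adjusted p = 0.598). Upp1 rose by 4.83 ± 0.24, Tbx3 fell by 2.11 ± 0.23 and Nr5a2 by 1.75 ± 0.20. Pou5f1, which encodes OCT4, had a change of 0.00 ± 0.19 (adjusted p = 0.993) that scaling to the hybridization controls turned into a called 1.02. Nanog had a change of 0.73 ± 0.28 (adjusted p = 0.0339), a call that ended without 8-cell replicate 1 (0.70), 8-cell replicate 3 (0.59), blastocyst replicate 1 (0.65) or blastocyst replicate 4 (0.51), and under quantile normalization (0.62) or the smaller pseudocount (0.75). Primitive endoderm markers had 9 of 22 higher and 4 lower, equal when adjusted over the list alone, and did not pass (adjusted p = 0.0711). That list was called higher under quantile normalization (adjusted p = 0.032), the larger pseudocount (0.0432), no filter (0.0468) and the stricter filter (0.042). Sox17 rose by 2.80 ± 0.30 and Lama1, a laminin of the endoderm basement membrane, by 2.61 ± 0.26. Gata6 fell by 0.74 ± 0.18, a direction that turned under scaling to the hybridization controls (0.29).

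Ribosome biogenesis genes had 27 of 45 lower and 0 higher, equal when adjusted over the list alone. Wdr43 fell by 2.44 ± 0.15 and Nolc1 by 1.97 ± 0.22, both nucleolar proteins. The list passed at 6.29e-06, with adjusted p = 0.201 with an estimated correlation, and its median of -0.67 became 0.32 under scaling to the hybridization controls. Ribosomal protein genes had 24 of 43 lower and 0 higher (25 and 0 adjusted over the list alone). Their median of -0.55 passed at 0.000735, with adjusted p = 0.563 with an estimated correlation. It was -0.06 and not called under quantile normalization and 0.49 and not called under scaling to the hybridization controls. Oocyte-specific genes had 16 of 24 lower and 1 higher (17 and 1 adjusted over the list alone), and passed at 1.42e-05 and with an estimated correlation (0.0347). Nlrp5 fell by 2.10 ± 0.21. The 2-cell activation genes had 9 of 14 lower and 1 higher, equal when adjusted over the list alone, with Sp110 lower by 3.36 ± 0.20. This list passed at 0.0242, with adjusted p = 0.158 with an estimated correlation, and its median of -0.65 became 0.12 under scaling to the hybridization controls. Proteasome genes had 13 of 36 higher and 1 lower, equal when adjusted over the list alone, and passed at 0.00151, with adjusted p = 0.451 with an estimated correlation; Psmd2 rose by 1.67 ± 0.20.

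DNA replication genes had 17 of 46 higher and 7 lower, equal when adjusted over the list alone. Uhrf1 rose by 2.42 ± 0.18 and Rpa1, a single-strand DNA-binding protein gene, by 1.82 ± 0.16. Camera called the list at 0.0315, with adjusted p = 0.177 with an estimated correlation, and the call ended under quantile normalization (0.189) and under the stricter filter (0.0803). The largest rises were those of Adh1, an alcohol dehydrogenase, by 5.66 ± 0.35, Gsta4, a glutathione transferase, by 5.50 ± 0.36, and the peptide transporter gene Slc15a2 by 5.07 ± 0.25. In the largest falls, Bex6 fell by 5.01 ± 0.21, Pdxk, pyridoxal kinase, fell by 4.74 ± 0.25 and Arg1, cytosolic arginase, fell by 4.39 ± 0.27. Foxa1, a forkhead factor, fell by 3.90 ± 0.29. Aurkc, an Aurora kinase of germ cells and early embryos, fell by 3.19 ± 0.15.

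Markers of other cell types formed no passing list at any transition. From the 8-cell stage to the blastocyst, cumulus and granulosa markers had 0 of 12 higher and 3 lower, equal when adjusted over the list alone (adjusted p = 0.187). Sperm and spermatid markers had 1 of 10 higher and 2 lower (1 and 1 adjusted over the list alone; adjusted p = 0.774). Oviduct, blood and leukocyte markers had 1 of 20 higher and 7 lower (1 and 4 adjusted over the list alone; adjusted p = 0.215). Wfdc2, an epithelial secretory gene, rose by 2.62 ± 0.35, beside the trophectoderm genes. Ovgp1 fell by 2.35 ± 0.68, and by 1.16 without 8-cell replicate 2, which had an intensity of 3105.

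In all, 7742 probe sets passed, 3359 higher and 4383 lower, and 3440 changed at least 2-fold, 1882 higher and 1558 lower. Of the lists, 10 of 21 passed, and the estimated correlation kept 3. The median, mean and test differed in sign for the chromatin modifier list, which did not pass (adjusted p = 0.569). The share of higher probe sets, 43.4% of those called, was 54.1% after centring on the array median and 94.9% of 7862 after scaling to the hybridization controls. These scalings moved the median of all genes by 0.13 and 0.83, and quantile normalization moved it by 0.12.

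**Figure D4:**
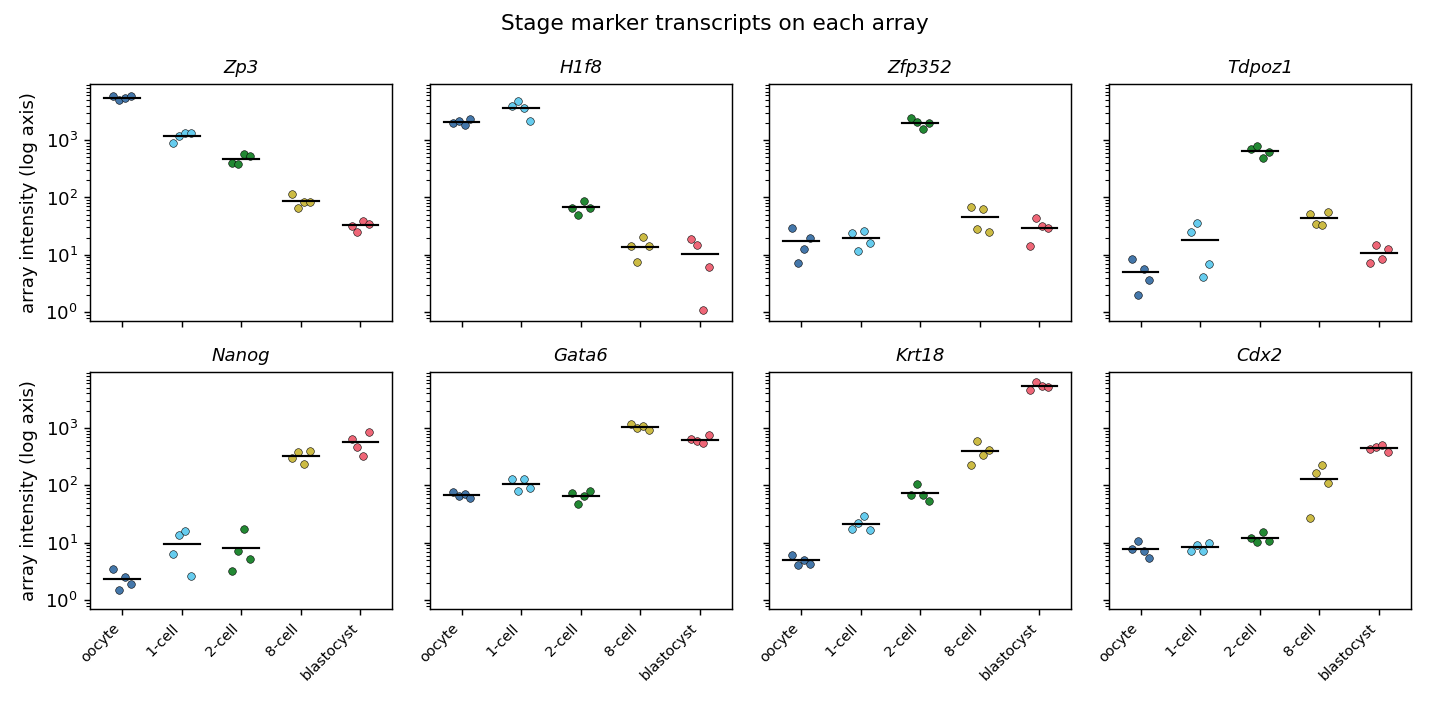
Array intensity (log axis, deposited scale) of 8 transcripts by stage, with 1 point per array and a line at the mean of 4. Krt18 reached a mean of 5346 in blastocysts and Zfp352 a mean of 1994 at the 2-cell stage. The fall of Gata6 from the 8-cell stage to the blastocyst and its rise from the oocyte to the 1-cell stage turn under scaling to the hybridization controls.

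Across the whole interval from oocyte to blastocyst, 10180 probe sets differed, 4897 higher and 5283 lower. Of the oocyte-specific genes, 23 of 24 fell, with a median log2 change of -5.82, and of the trophectoderm markers 24 of 27 rose, with a median of 2.57, both equal when adjusted over the list alone. Pluripotency markers had 15 of 23 higher and 3 lower, equal when adjusted over the list alone, with a median of 1.29. These 3 lists passed at adjusted p of 7.9e-17, 2.77e-12 and 2.17e-05 and held with an estimated correlation (0.00143, 0.00921 and 0.00536). Nlrp5 fell by 8.21 ± 0.21 and Zp3 by 6.95 ± 0.18, while Krt18 rose by 8.29 ± 0.23, Nanog by 5.24 ± 0.28 and Cdx2 by 4.53 ± 0.33 (SE, n = 4 arrays per stage). Dnmt1 fell by 3.96 ± 0.18 and Dnmt3b rose by 3.12 ± 0.19.

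Ribosomal protein genes had 39 of 43 higher and 0 lower (39 and 1 adjusted over the list alone; adjusted p = 4.45e-14, and adjusted p = 0.143 with an estimated correlation). Oxidative phosphorylation genes had 54 of 71 higher and 3 lower (56 and 3 adjusted over the list alone; adjusted p = 1.1e-09, and adjusted p = 0.156 with an estimated correlation). M phase genes had 22 of 37 lower and 4 higher, equal when adjusted over the list alone (adjusted p = 0.00416, and adjusted p = 0.0805 with an estimated correlation). Of the lists, 13 of 21 passed over this interval and the estimated correlation kept 3. The median, mean and test differed in sign for the 2-cell activation, DNA replication and oviduct lists, none of which passed. The median of all genes moved by -0.25 under scaling to the hybridization controls, which gave 37.9% higher of 9793 called against 48.1%.

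Ribosomal protein genes were also common among transcripts that fell at the 1-cell stage and rose again at the 2-cell stage, a course counted after the lists had been seen. Of 2639 probe sets that fell, 1325 rose again, where independent lists would share 612, and probe sets fallen at 1-cell and risen at 2-cell numbered 2462 under scaling to the hybridization controls. Both comparisons use the 1-cell arrays, so anything particular to these arrays gives a fall and then a rise. With the 1-cell arrays divided between both comparisons, 1026 to 1060 were shared. Dividing them does not remove what all of them have in common, and no count for independent lists was made for the divided arrays. At an unadjusted p under 0.05 the count was 1583, against 90.1 on average over 50 draws simulated without stage effects. Those draws hold no changed probe sets, so they do not give the overlap to expect of long lists. Of the ribosomal protein genes 36 of 43 had this course, of the oxidative phosphorylation genes 30 of 71, of the ribosome biogenesis genes 17 of 45, of the proteasome genes 9 of 36 and of the DNA replication genes 10 of 46, against 793 of all 10257 genes. No test of these counts is given, since the course was chosen from the changes of the ribosomal protein list.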

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

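The tests in this part were chosen after related results had been seen, except the test of histone genes, which was written before histone values were seen, and the screen for single arrays, which was fixed in advance. The second test of Ovgp1 was written after the values of its markers had been seen.

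Ribosomal protein and oxidative phosphorylation transcripts were lower at the 1-cell stage than in the oocyte. The 10 genes of small Sm and Lsm proteins had a median log2 change of 0.0093 (95% bootstrap interval -0.96 to 0.85), above the -2.09 of the ribosomal list. This argues against a loss of all short transcripts alike during amplification. The genes moved both ways, from -2.298 for Snrpc to 1.365 for Snrpd3, so a loss of some short transcripts remains open. Transcript lengths were not compared. Scaling of the arrays, or equal dilution of all mRNA by ribosomal RNA, would move all genes alike. Such a shared shift is argued against for the ribosomal list, which lay -2.18 from all other genes (95% bootstrap interval -2.85 to -1.74). Both intervals resample genes, which can vary together, and do not measure the spread between arrays. The gap of -2.18 restates the list result that raised the question, so it is not a separate test. Under quantile normalization the ribosomal list stayed at -2.16, with all genes at 0.09 and the oxidative phosphorylation list at -1.66. Loss that depends on the poly(A) tail and a change with the stage itself remain open and were not tested. A fall that is specific to these transcripts is therefore a hypothesis, found and tested on the same arrays.

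The signal of the middle probe set of 18S ribosomal RNA was 12670 ± 1877 at the 1-cell stage (SD, n = 4), 64.7 times that of the oocyte and 14.9 times that of the 8-cell stage, against 25.0 and 7.11 times for the 3′ and 21.9 and 6.01 times for the 5′ probe set. Dim arrays scaled up are argued against, since the 18S signal relative to the cre control was higher at the 1-cell than at the 8-cell stage, by a ratio of 20.2 for the middle probe set (14.4 to 28.5 over pairs of single arrays), 10.1 for the 3′ (6.21 to 19.7) and 8.37 for the 5′ probe set (5.12 to 24.6). Wider amplification of RNA without a poly(A) tail is argued against by replication-dependent histone probe sets, with a median log2 change of 0.10 (95% bootstrap interval -0.47 to 0.46, 13 probe sets, of which 2 rose and 1 fell). This holds only if the histone transcripts did not themselves fall between these stages, which the arrays cannot show. Their changes ran from -2.94 to 1.24, and some probe sets stand for the same gene, which the interval ignores. Carry-over of ribosomal RNA in the preparation of these 4 arrays and a change with the stage itself cannot be separated, since no label gives a preparation batch, and neither was tested.

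Ovgp1, the oviduct glycoprotein gene, averaged 495 ± 242 at the 2-cell and 865 ± 1495 at the 8-cell stage (SD, n = 4), the latter 118 without replicate 2, against 58.5 ± 26.9 in oocytes. Oviduct cells or their secretions carried over with the embryos may be the source, since Ovgp1 correlated with the mean of 4 other oviduct markers over the 8 arrays of both stages at r = 0.748 (exact permutation p = 0.0387, 95% interval 0.0914 to 0.951, rho = 0.81, exact permutation p = 0.0218, 2-sided, and r = 0.779 without the 2 farthest arrays). With the mean of each stage removed, r was 0.73 and did not pass (exact permutation p = 0.208 over 576 pairings within stages, r = 0.522 without the 2 farthest arrays), while the arrays of each stage had the same order in both measures (rho = 1, exact permutation p = 0.00347, the smallest these pairings can give). Adjusted over these 4 tests, p was 0.0516 for the pooled r, 0.0436 for the pooled rho, 0.208 for r without the stage means and 0.0139 for rho without them. The median change of these 4 markers from the 1-cell to the 2-cell stage was -0.056 (95% bootstrap interval over markers -0.35 to 1.38), which leaves the source open, and expression by the embryo and cross-hybridization of a probe set that other transcripts may share were not tested. No correlation with markers of an unrelated cell type was computed, so the relation is not shown to be particular to oviduct markers. On 8-cell replicate 4, the cumulus list (-0.37 from the oocyte mean) and Ovgp1 (46.5) were both lowest of their stage. On 2-cell replicate 1, the cumulus list was lowest (-0.36) and Ovgp1 highest (764.6).

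The other results are arrays far from the rest of their stage, given as the gap to the nearest array over the range of the 4 arrays. Chance marks about 1 in 20 groups, 37 of the 741 examined, and 39 were marked. On 8-cell replicate 4, which had the most, the gap was 0.896 for Gyg, 0.862 for Bcl7c, 0.884 for Eif1a, 0.886 for Aqp9, 0.899 for Tdgf1, 0.841 for Nolc1, 0.849 for Psma7 and 0.839 for Cdc6. On 1-cell replicate 4 it was 0.871 for Ccnl1, 0.834 for Rnf10, 0.959 for Crxos, 0.857 for Mos and 0.927 for Papola. On 1-cell replicate 1 it was 0.882 for Noc4l, 0.896 for Cyp51, 0.92 for Pabpc1 and 0.892 for the cre control, and on 1-cell replicate 3 it was 0.886 for Ldhc.

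Among 2-cell arrays, the gap on replicate 3 was 0.868 for U2af1, 0.903 for Slc16a1, 0.902 for Hk2 and 0.856 for Sox2. It was 0.849 for Id3 and 0.93 for Ndufab1 on replicate 1, 0.921 for Tspan1 and 0.888 for Cyp51 on replicate 2, and 0.932 for Prpf6 on replicate 4. Among 8-cell arrays it was 0.935 for Gsta4 and 0.922 for Hspa1b on replicate 2 and 0.84 for Psme4 on replicate 1. Among oocyte arrays it was 0.837 for Nrp1, 0.892 for Serpinh1 and 0.953 for Cdc6 on replicate 3, 0.884 for Cox17 and 0.928 for Fdft1 on replicate 4, 0.833 for Rrm2 on replicate 1 and 0.933 for the Gapdh ratio of 3′ to 5′ signal on replicate 2. Among blastocyst arrays it was 0.878 for Dppa3 on replicate 3 and 0.898 for Wdr43 on replicate 4.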

How the results depend on the processing

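Scaling to the hybridization controls, and the count of transcripts that fell at the 1-cell and rose at the 2-cell stage, were chosen after the data had been seen; the other settings were planned. Requiring a 2-fold change left 2420, 4676, 5064 and 3440 probe sets at the consecutive transitions, while 1 probe set per gene, which tests fewer of them, left 3276 probe sets changed oocyte to 1-cell, 4586 probe sets changed 1-cell to 2-cell, 4909 probe sets changed 2-cell to 8-cell, 4805 probe sets changed 8-cell to blastocyst and 6140 probe sets changed oocyte to blastocyst. An estimated correlation kept 13 of 47 list calls. Scaling to the controls raised the probe sets fallen at 1-cell and risen at 2-cell from 1325 to 2462. It moves whole arrays by construction and turned 26 results of single genes. From oocyte to 1-cell these were Tcl1 -0.040, Pou5f1 -0.25, Gata6 -0.34, Pa2g4 -0.057, Hk2 -0.18, Pgk1 -0.48, Stard4 -0.25, Bcl2l11 -0.33, Mdm2 -0.48, Gdf9 -0.74 (called, adjusted p = 0.0214), Dppa3 -0.38, Dnmt3b -0.43, Sox2 -0.22, Cdx2 -0.39 and Krt8 -0.69. From 8-cell to blastocyst they were Snrpc 0.14, Srsf1 0.21, Psma6 0.41, Lss 0.48, Amot 0.073, Mark2 0.21, Suz12 0.16, Acr 0.20, Gata6 0.29 and Mos 0.0072, and from 2-cell to 8-cell Dppa3 -0.44. Quantile normalization turned Dppa3 from 2-cell to 8-cell to a called -0.81 and, without a call, from 1-cell to 2-cell to 0.18, Gdf9 from oocyte to 1-cell to -0.26, Cdx2 there to -0.028, Sox2 from 2-cell to 8-cell to 0.0021 (0.023 with median centring) and Pou5f1 from 8-cell to blastocyst to -0.10. The cause was not tested.

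No called list turned in its camera direction. Lists that were not called either way turned, with these medians. From 1-cell to 2-cell these were cholesterol synthesis (0.354 with quantile normalization, 0.353 with median centring, 0.556 with the smaller pseudocount, and 0.47 without a filter, without the trend and with the block), proteasome (-0.0765 with the smaller pseudocount, -0.0741 with the stricter filter) and cumulus markers (-0.0762 with the stricter filter, -0.135 with the block). From oocyte to 1-cell they were primitive endoderm (0.111 with median centring, 0.0871 with the larger pseudocount, 0.254 with the stricter filter, -0.714 with the controls), cholesterol synthesis (-0.709 with the controls) and M phase (-0.744 with the controls). From 8-cell to blastocyst they were splicing factors (0.0027 with median centring, -0.13 without a filter, 0.904 with the controls), M phase (0.909 with the controls) and sperm markers (-0.527 with the stricter filter). The others were primitive endoderm from 2-cell to 8-cell (-0.403 with the controls) and, from oocyte to blastocyst, 2-cell activation genes (0.0202 with the larger pseudocount) and oviduct markers (-0.418 with the stricter filter).

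Leaving out each replicate gave 4682 to 5425, 7007 to 7574, 7640 to 8302 and 6554 to 8121 probe sets at the consecutive transitions, 9576 to 10150 from oocyte to blastocyst, 938 to 1094 transient at the 2-cell stage and 1187 to 1427 fallen and risen. Uncalled changes that turned ranged from -0.018 to 0.11 for Cdx2, -0.093 to 0.38 for Krt8 and -0.21 to 0.085 for Cdh1 from oocyte to 1-cell, -0.29 to 0.041 for Nanog from 1-cell to 2-cell, -0.026 to 0.24 for Dppa3 and -0.18 to 0.10 for Sox2 from 2-cell to 8-cell, and -0.073 to 0.11 for Pou5f1 from 8-cell to blastocyst. Of the 405 gene results, 23 lost their call without some replicate. With the replicate number as a block the counts were 5403, 7698, 8310, 7688 and 10206, and only 7 of 20 arrays correlated best with arrays of their own number. Low signal limits genes near the filter.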

Other observations

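The counts over other divisions of the arrays were planned, and what they were set against was written after the calls had been seen; the genes named in the next paragraph were chosen after their values were seen.

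Several transcripts were highest at the 2-cell stage. Dr1, a repressor of RNA polymerase II transcription, had an intensity of 51 ± 6.34 at the 1-cell stage, 1450 ± 139 at the 2-cell stage and 69.4 ± 10.8 at the 8-cell stage (SD, n = 4). Spz1, a transcription factor gene of the testis, went from 5.83 ± 2.37 to 730 ± 179 and back to 37.1 ± 3.75. Obox3, an oocyte homeobox gene, was at 83.9 ± 27 at the 1-cell, 913 ± 124 at the 2-cell and 32.2 ± 5.13 at the 8-cell stage. Fundc1, a mitophagy receptor gene, was at 182 ± 23.4, 2638 ± 1012 and 82.2 ± 20. All rose to the 2-cell stage and fell by the 8-cell stage in limma's test, with adjusted p of 8.12e-12 or lower for the rise and 2.62e-13 or lower for the fall.

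Control probe sets outside the comparisons also differed between stages. The 3′ probe set of the transferrin receptor gene averaged 19.9 in oocytes, 25.6 at the 1-cell, 721 at the 2-cell and 315 at the 8-cell stage, and 27.1 in blastocysts. The B2 repeat probe set averaged 5993 ± 618 in oocytes and 17490 ± 3636 at the 8-cell stage. From oocyte to blastocyst its means were 5993, 10930, 11320, 17490 and 8376, near those of the cre control, 6202, 12080, 10360, 16280 and 7467. A change of B2 apart from the scaling of the arrays is therefore not shown. The B1 repeat probe set averaged 2389 ± 567 in oocytes, 1564 ± 589 at the 8-cell stage and 939 ± 352 in blastocysts. The cre control, which is added in a fixed amount, was 2.62 times as high at the 8-cell stage as in oocytes.

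The counts of changed probe sets were set against other divisions of the same arrays. In each comparison, 1 of the 35 divisions of the 8 arrays into groups of 4, the real one, gave as many. A share of 1 in 35 is the smallest possible, so chance is not excluded. Every other division puts arrays of both stages into each group. The differences between stages then widen the spread, so low counts there were set in advance. A difference in preparation between the stages would give the same result. The real division gave 5527 probe sets from oocyte to 1-cell, 7597 from 1-cell to 2-cell, 7966 from 2-cell to 8-cell, 7015 from 8-cell to blastocyst and 10474 from oocyte to blastocyst, and the highest of the others gave 0. At an unadjusted p under 0.05 in limma's test, the real division gave 6980, 8637, 8972, 8622 and 11037, and the highest of the others 2134, 2019, 1433, 2809 and 2159.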
